A study of Mus musculus with 30 samples.

How the data were processed

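RNA from 5 successive EDTA fractions of small intestinal epithelium, taken from 3 vehicle mice and 3 ICZ mice, was sequenced from 3' end libraries. The authors deposited 1 table of read counts per gene, with 54146 genes and 30 sample columns, and its values are whole-number counts that were not normalized. Reads were aligned with BWA 0.7.17-r1188 and counted with HTSeq 0.11.2, with SAMtools 1.10 and FastQC 0.11.2 also named, per the submitters' processing notes, which name the mouse build GRCm38.p6 (mm10). The annotation release, the strand setting of the counting and the use of molecular identifiers are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart, and without molecular identifiers reads are not independent molecules, so that counting intervals and floors cover counting error only. BWA does not split reads over introns, and HTSeq leaves out reads of low mapping quality, so genes with near-identical copies, such as ribosomal protein genes, defensins, Hspa1a and Hspa1b or the actins, are uncertain. Muc2, the main goblet cell mucin, had 0 reads in all 29 libraries although its annotation is among the counted genes.

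The table ends with 5 summary lines that name no gene, which stayed out of library sizes and tests. Over the 29 assigned libraries reads assigned to genes made up 51.6% to 61.6% of all counted reads, reads without a feature 9.16% to 14.7%, ambiguous reads 3.61% to 5.10%, reads of too low alignment quality 18.0% to 26.5% and unaligned reads 2.63% to 7.31%. All counted reads came to between 7832280 and 13715519 per library, and gene reads to between 4359673 and 7819837. At this depth a gene of 0 reads can still be expressed below a few reads per library. Gene identifiers with their version matched GENCODE M21 in 52480 cases and without it in 54079, and coordinates are GRCm38 positions from that annotation, counted from 1. Symbols come from the deposited table; 59 symbols are given to more than 1 gene, and 22925 genes had 0 reads in the assigned libraries.

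Samples were assigned to treatment, fraction and replicate from their labels. No F1 library of ICZ replicate 3 was analysed here, and a sample labelled as undetermined was kept out of every comparison. Replicate libraries were compared first: over 28 pairs within groups the chi-square per degree of freedom lay between 5.08 and 111 and the correlation of log2 CPM across genes between 0.931 and 0.987, so none agreed within sampling noise and each counted as 1 replicate. The 5 fractions of a mouse come from the same animal. Deviations from group means correlated at 0.169 on average between fractions of a mouse and at -0.084 between mice of a treatment. Such deviations cancel within a group, so the negative value follows from the centring and is no separate support. The first principal component held 29% of the variance and the second 12%.

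The tests, alternatives, gene lists and the rule for named genes were set before the data were examined, except those named below as chosen later. Each comparison used edgeR 4.0.16 on the deposited counts: genes kept by filterByExpr, TMM normalization, robust quasi-likelihood dispersion, and the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. ICZ was compared with vehicle on counts of F2 to F5 added per mouse, since all 6 mice have these fractions, and within each fraction, without a block. Differences of the ICZ effect between fractions were tested in all 29 libraries with the mouse as a block, as 4 treatment by fraction terms together and as a slope over fraction number. F5 was compared with F1 in the 15 vehicle libraries with the mouse as a block. Standard errors were taken as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. Log2 CPM used a prior count of 2. Means are CPM computed here with TMM library sizes, with the SD over mice. Exact permutation tests were two-sided, and for 3 mice against 3, or 3 against 2, their smallest p is 0.1. Ratios of pooled reads have exact 95% intervals.

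The genes to be named in the summed comparison were 9 AHR genes (Cyp1a1, Cyp1a2, Cyp1b1, Ahrr, Tiparp, Nqo1, Aldh3a1, Ahr and Arnt), then up to 10 genes per direction with the largest absolute log2 fold change among those past the threshold, with a mean of at least 5 CPM in a group and no overlap between groups, leaving out predicted genes. Up to 4 members of smallest p per gene list served as examples. Single fractions used up to 5 genes per direction, F5 against F1 up to 10, and the tests between fractions up to 10 genes of smallest p. Acta1 and Mbl2 in the summed comparison, and examples given with values outside the rule, were chosen after their values were seen.

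Gene lists numbered 33, and 4 of their genes are not among the table's symbols. They cover the AHR battery, NRF2 targets, other xenobiotic metabolism, stem cells, proliferation, Wnt and Notch genes, goblet, Paneth, enteroendocrine and tuft cells, absorptive enterocytes, the villus tip and lower villus antimicrobial genes. Further lists hold genes of fat absorption, cholesterol synthesis, PPAR targets, retinoid metabolism, amino acid response and ER stress, interferon response, MHC class II, the circadian clock, and immediate early and dissociation stress. Lists of intraepithelial T cells, B and plasma cells, macrophages and dendritic cells, stroma with endothelium and muscle, red cells and pancreatic acinar cells stand for other cell types, and lists of proximal and distal intestine, mitochondrial and cytosolic ribosomal protein transcripts complete the set. Lists with at least 3 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, again with a correlation estimated for each list, and with fry. Fos and Junb stand in both the villus tip and the stress list.

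The replicate numbers of the labels were checked for pairing before the calls of the fits with and without a block were compared. In the summed counts same-numbered vehicle and ICZ mice had deviations from their group means correlated at 0.247 to 0.472 across genes, against at most -0.025 for other pairs; in F2 the range was 0.101 to 0.153 against at most -0.02. In these 2 comparisons every same-numbered pair lay above 0.1, so the numbers were taken to pair the mice. This was taken from the data, since the labels state no shared litter or day. Sample labels also carry a separate mouse number, whose meaning is not stated. It is the same for vehicle and ICZ within 2 of the same-numbered pairs and differs within the pair of replicate 1. The labels thus give no sign of pairing for replicate 1, which the block nevertheless treats as a pair. Deviations from a group mean cancel within a treatment, so the lower values of other pairs are no separate support. The best of 6 possible matchings can also arise by chance, and blocked results rest on this assumed pairing. In F4 another matching had a higher mean correlation, 0.172 against 0.113 for the same numbers. In F3, F4 and F5 at least 1 pair lay lower, at 0.032, 0.028 and -0.06, and F1 has only 2 pairs. The fit with the replicate number as a block is given beside the summed and F2 results where it changed a call.

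Each procedure was tested on simulated counts with 200 changed genes, drawn from the means, library sizes and dispersions of the real samples. Counts were drawn independently, without mouse, pair or fraction effects, so the recovered shares may not hold for the real data. Of genes changed by a log2 fold change of 1 and of 2, the summed comparison recovered 69.1% and 92.9% (15497 genes), F1 51% and 87.5% (12335 genes), F2 62.2% and 94.9% (12115 genes), F3 57% and 89.2% (12268 genes), F4 59.2% and 97.9% (12092 genes), F5 22.1% and 85.3% (12244 genes) and F5 against F1 59.2% and 85.9% (13164 genes). False calls made up 6.5%, 8.9%, 9.4%, 7.3%, 6.7%, 13.6% and 5.9% of calls in that order, above the nominal 5%. The interaction test recovered 35.7% and 69.7% with 11.1% false calls, and the slope test 39.4% and 74.7% with 1.7% (14067 genes each). For the slope test the simulated changes were totals from F1 to F5, with median estimates of 0.25 and 0.49 per fraction.

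Alternatives were RLE size factors, no filter on low counts beyond 1 read, DESeq2 1.42.0, the replicate block, a crypt-villus score per sample as a covariate (mean log2 CPM of enterocyte genes minus that of proliferation genes), leaving out each mouse, 1 fit over all 29 libraries, adding all available fractions, thinning libraries to 1 total before adding, and limma voom with the mouse as a correlated block. For the tests between fractions they also included F2 to F5 only and no mouse block, and for F5 against F1 the ICZ mice. Computation used R 4.3.3, Python with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for figures.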

Results

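Gene expression was measured in epithelium released from the small intestine of female C57BL/6J mice after gavage with indolo[3,2-b]carbazole (ICZ), a ligand of the aryl hydrocarbon receptor (AHR), a transcription factor activated by dietary and environmental indoles. Mice kept on a purified diet received 10 µg of ICZ in corn oil or the oil alone, and tissue was taken 12 h later. The epithelium of each mouse was released by EDTA in 5 successive fractions, F1 to F5, and 3' end RNA sequencing libraries were made from each. The labels give the order of release and leave open which part of the crypt-villus axis each fraction holds. Vehicle mice gave 15 libraries, from 3 mice with 5 fractions each. ICZ mice gave 14, since an F1 library of ICZ replicate 3 was not analysed here. A sample whose label names neither treatment nor fraction entered no comparison. The 29 assigned libraries held between 4359673 and 7819837 reads assigned to genes, with a median of 6351137. The median was 6694710 over the vehicle libraries and 6199234 over the ICZ libraries, and between 17801 and 20881 genes were detected per library. In the F5 library of ICZ replicate 1 the 10 most abundant genes took 54.3% of gene reads, against a median of 26.8% over all 29 libraries.

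F5 was set against F1 in the vehicle mice to describe what the fractions hold without treatment. Genes of absorptive enterocytes, the nutrient-absorbing cells of the villus, were lower in F5. Of 21 tested members 18 fell and 0 rose, among them the fructose transporter Slc2a5, from 403 ± 92.7 CPM (read counts scaled to library size) in F1 to 138 ± 53.1 in F5, and the fatty acid binding protein Fabp1, from 4798 ± 1010 to 2137 ± 816 (SD, n = 3 mice each). Proliferation genes went the other way: 27 of 29 rose in F5, including the thymidylate synthase Tyms, from 11.8 ± 3.11 to 27.4 ± 4.01 CPM, and the centromere histone Cenpa, from 11.8 ± 4.38 to 32.9 ± 6.94 CPM. Stem cell genes rose in 13 of 16 cases, with Lgr5, a receptor for R-spondins that marks intestinal stem cells, at 4.15 ± 0.81 CPM in F1 and 11.7 ± 4.2 in F5 and Smoc2 at a log2 fold change of 1.55 ± 0.24 (SE). Immediate early and heat shock genes, which respond to dissociation of a tissue, rose in 16 of 17 cases, and Hspa1a, an inducible HSP70 chaperone, went from 4.39 ± 3.32 to 96.2 ± 42.9 CPM. In edgeR's quasi-likelihood test with the mouse as a block, 3703 of 13164 tested genes passed an adjusted p of 0.05, 1959 higher and 1744 lower in F5. The count fell to 886 without vehicle replicate 3 and to 1929 without vehicle replicate 2.

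**Figure D1:**
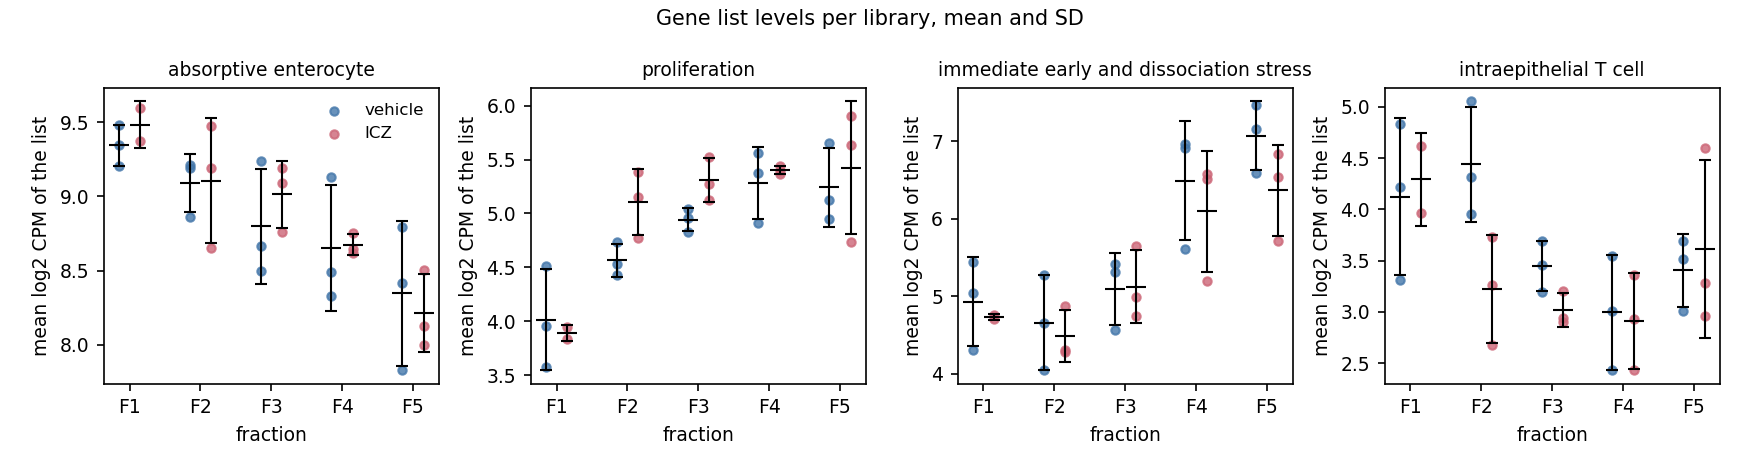
Mean log2 CPM of 4 gene lists in each library, by fraction (F1 to F5) and treatment; points are libraries, 1 per mouse and fraction, with horizontal lines at group means and error bars of 1 SD. In vehicle mice the mean of the enterocyte list goes from 9.34 in F1 to 8.35 in F5, that of the proliferation list from 4.01 to 5.24.

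The largest log2 fold changes under the rule for named genes were those of the AP-1 subunit Fosl1 (6.59 ± 0.89), Hspa1a (4.69 ± 0.43), the nuclear receptor Nr4a1 (4.26 ± 0.46), the matrix protein gene Thbs1 (4.08 ± 0.64), Arc (4.05 ± 0.59), Klf2 (3.97 ± 0.37), Hspa1b (3.88 ± 0.25), C2cd4b (3.51 ± 0.69), Timp3 (3.47 ± 0.57) and Egr1 (3.30 ± 0.29) among genes higher in F5. Susd2 (-2.74 ± 0.29), Pmp22 (-2.50 ± 0.41), the carotenoid-cleaving enzyme gene Bco1 (-2.39 ± 0.35), Lpar3 (-2.36 ± 0.48), Ttll2 (-2.27 ± 0.46), Clca4a (-2.15 ± 0.51), Fbxo44 (-2.09 ± 0.41), Paqr9 (-2.07 ± 0.27), S100a6 (-1.94 ± 0.27) and Slc46a3 (-1.91 ± 0.28) were the counterparts in the lower direction. Each of these 20 genes passed the edgeR test with no overlap between the 3 F5 and the 3 F1 values, and the adjusted p of Clca4a came to 0.184 without vehicle replicate 3 and 0.0506 without vehicle replicate 1. Without the mouse block Susd2 (adjusted p = 0.0551), Pmp22 (0.112), Bco1 (0.0719), Clca4a (0.186) and Paqr9 (0.0522) missed the threshold. In the ICZ mice Fosl1 (0.378), C2cd4b (0.0591), Ttll2 (0.0615) and Fbxo44 (0.0823) did so, and Thbs1 (0.172) when F4 was set against F1. Over the alternatives the adjusted p of these 10 genes lay between 1.22e-28 and 0.378.

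By the camera gene set test, 19 of 31 tested lists differed between F5 and F1, 8 higher and 11 lower in F5. The list of immediate early and dissociation stress genes had a median log2 fold change of 1.86 and an adjusted p of 2.98e-38, and it alone held with an estimated correlation, at an adjusted p of 0.0105. The proliferation list (median 1.27), the stem cell list (1.19), the Wnt list (1.00, 10 of 14 higher, including Ccnd1 at 1.13 and Cd44 at 1.19) and the ribosomal protein list (0.90, 26 of 32 higher) were each called higher, with adjusted p = 0.209 with an estimated correlation for each of the 4. Paneth cell genes were higher in 10 of 11 cases, with the defensin Defa17 at 1215 ± 430 and 2785 ± 1460 CPM and the angiogenin Ang4 at 1.03 ± 0.23 (adjusted p = 0.292 with an estimated correlation). Amino acid response and ER stress genes were higher in 8 of 15 cases, led by the stress transcription factors Ddit3 (2.17 ± 0.17) and Atf3 (2.94 ± 0.29), while Trib3 fell (-1.51 ± 0.24; adjusted p = 0.106 with an estimated correlation). Cholesterol synthesis genes had a median of 0.33, with 9 higher and 1, Sc5d, lower out of 24 (adjusted p = 0.262 with an estimated correlation).

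Among the lists lower in F5, absorptive enterocyte genes had a median log2 fold change of -1.07 (adjusted p = 1.81e-17 by camera; adjusted p = 0.132 with an estimated correlation). Genes of fat absorption and chylomicrons fell in 15 of 17 cases, with the fatty acid transporter Slc27a4 at -1.09 ± 0.13 (adjusted p = 0.106 with an estimated correlation). Goblet cell genes fell in 6 of 13 cases and rose in 1; the secreted proteins Zg16 (6858 ± 855 to 2093 ± 623 CPM) and Tff3 (2309 ± 390 to 984 ± 64 CPM) were among those that fell (adjusted p = 0.106 with an estimated correlation). Villus tip genes fell in 8 of 16 cases, including the ectonucleotidase Nt5e (-1.90 ± 0.30), and 3 rose, including Fos and Junb, which also respond to dissociation (adjusted p = 0.354 with an estimated correlation). Interferon response genes fell in 10 of 19 cases, with Isg15 at 69.1 ± 7.6 and 21.8 ± 9.16 CPM (adjusted p = 0.262 with an estimated correlation). Xenobiotic metabolism genes outside the AHR list fell in 10 of 21 cases, including Cyp2b10 and Cyp2j6 (adjusted p = 0.209 with an estimated correlation). Lists of NRF2 targets (5 lower and 1 higher of 13) and tuft cells (4 of 9 lower) were called at smaller medians of -0.30 and -0.54, with adjusted p = 0.262 with an estimated correlation for both. The distal intestine list (5 of 7 lower, 1 higher), the proximal list (3 of 10 lower) and the intraepithelial T cell list (1 of 17 lower, Nkg7) were called lower, with adjusted p = 0.13, adjusted p = 0.395 and adjusted p = 0.532 with an estimated correlation. Adjusted over the list alone, all 29 proliferation and all 16 stem cell genes rose, 18 of 21 enterocyte genes fell and 16 of 17 immediate early genes rose. For Notch and lineage genes the median was -0.11 and the mean -0.02 while the camera direction was up (adjusted p = 0.842).

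ICZ was set against vehicle to find which genes responded to the AHR ligand. Cyp1a1, the AHR target that encodes a monooxygenase able to clear such ligands, was nearly silent in vehicle mice and abundant in every ICZ library. Over F2 to F5 added per mouse it stood at 0.0543 ± 0.0671 CPM with vehicle and 38.9 ± 32.2 CPM with ICZ (SD, n = 3 mice each). The pooled reads, 4 and 2768, gave a ratio of 740 with a 95% counting interval of 289 to 2720. Without ICZ replicate 1 the ratio was 422, and without vehicle replicate 1, on 1 vehicle read, 2020. The ICZ mice stood at 75, 28.4 and 13.4 CPM. Its neighbour and paralogue Cyp1a2 had 0 reads in all vehicle libraries and 2.83 ± 0.94 CPM with ICZ, at least 75.5-fold higher against a floor of 3 reads over the vehicle group, and at least 48.1-fold without vehicle replicate 2. Nqo1, a quinone reductase controlled by AHR and NRF2, had 12.9 ± 2.4 CPM with vehicle and 19.1 ± 1.64 with ICZ, with no overlap between mice and a pooled ratio of 1.46 (1.35 to 1.59). Its ratios in F1 to F4 were 1.41, 1.89, 1.49 and 1.54. In F5 the Nqo1 ratio was 1.09 (0.923 to 1.28), and the mice overlapped there. Intervals and floors cover counting error only.

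In edgeR without a block none of these 3 genes passed over all genes, with adjusted p = 0.825 for Cyp1a1, 0.0535 for Cyp1a2 and 0.846 for Nqo1. When the replicate number was a block all 3 rose, with adjusted p = 2.01e-13, 2.45e-05 and 0.00945. Over the alternatives the adjusted p of Cyp1a1 lay between 2.01e-13 and 1, that of Cyp1a2 between 4.01e-24 and 0.459 and that of Nqo1 between 0.00945 and 1; without ICZ replicate 1 those of Cyp1a1 and Cyp1a2 were both 0.0111, and without vehicle replicate 1 that of Cyp1a2 was 0.0403. The exact permutation p was 0.1 for each of the 3 genes (two-sided, n = 3 and 3), the smallest that 3 mice against 3 allow. Cyp1a1 (ENSMUSG00000032315.6) lies on chromosome 9 at 57687928 to 57703824 on the plus strand and Cyp1a2 (ENSMUSG00000032310.4) at 57676937 to 57683703 on the minus strand, in GRCm38 with the GENCODE M21 annotation.

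In the summed counts other AHR genes showed no such difference. Tiparp, an ADP-ribosyltransferase that limits AHR signalling, stood at 67.8 ± 9.25 CPM with vehicle and 59.8 ± 6.94 with ICZ, with an adjusted p of 0.893 by edgeR. The AHR repressor gene Ahrr had 47 reads over the vehicle mice and 26 over the ICZ mice, a ratio of 0.591 (0.351 to 0.974), and Cyp1b1 had 4 and 0. No reads of Aldh3a1 were counted in either group, so a difference was not detectable at this depth. The receptor gene Ahr had 8.34 ± 1.19 and 9.14 ± 0.241 CPM. Its partner Arnt had 16.3 ± 3.12 and 15.6 ± 1.3 CPM, a log2 fold change of -0.06 whose sign was positive in 3 alternatives. By fraction, pooled ratios of Ahr were 1.65 (1.3 to 2.09) in F1 and 1.33 (1.07 to 1.66) in F4, and 0.944 to 1.07 elsewhere. That of Tiparp was 0.672 (0.618 to 0.73) in F5 and 0.859 to 1.07 elsewhere. These F1, F4 and F5 values had no overlap between mice. Ahrr had 15 reads with vehicle and 0 with ICZ in F2. Of the 7 tested genes of the AHR list 0 passed over all genes in the summed counts and 3 adjusted over the list alone. The list was called higher by camera (median 0.22, mean 2.62, adjusted p = 2.54e-09; adjusted p = 0.127 with an estimated correlation).

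**Figure D2:**
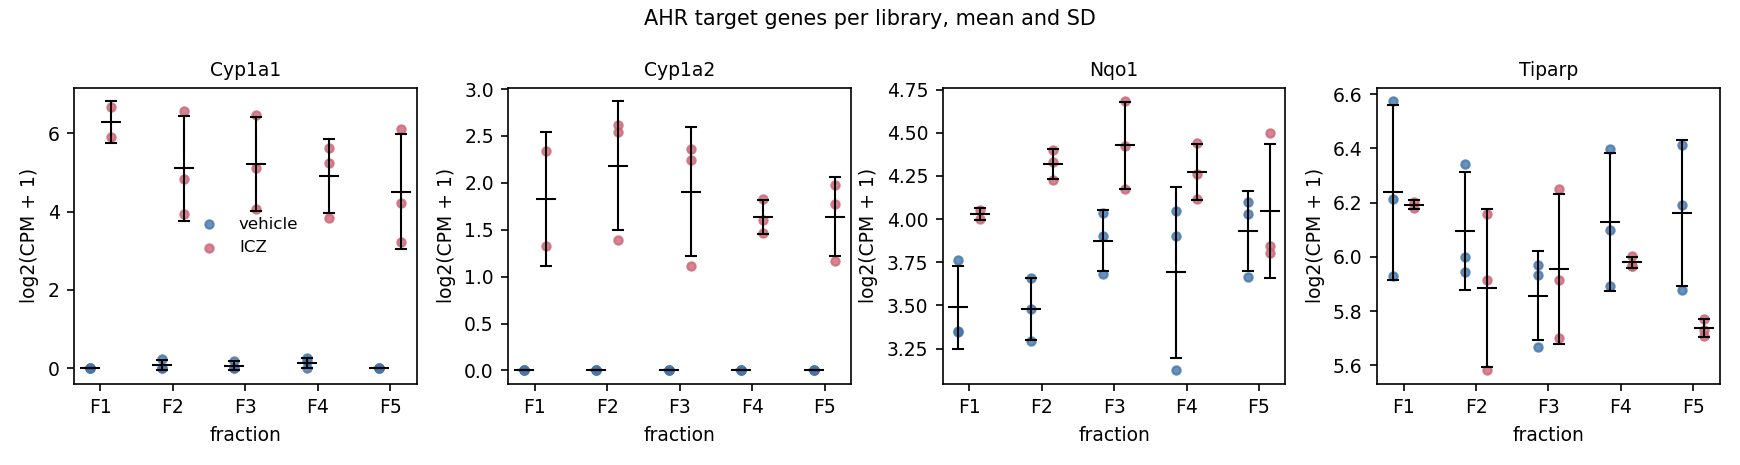
Log2(CPM + 1) of Cyp1a1, Cyp1a2, Nqo1 and Tiparp in each library, by fraction and treatment; points are libraries, 1 per mouse and fraction, with horizontal lines at group means and error bars of 1 SD. No vehicle library exceeds 0.191 CPM of Cyp1a1, and the ICZ libraries lie between 8.27 and 99.9 CPM.

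Cyp1a1 was also measured fraction by fraction. In F1 it had 0 reads with vehicle (n = 3) and 79.6 ± 28.7 CPM with ICZ (n = 2), at least 494-fold higher. The ICZ means in F2, F3, F4 and F5 were 45.1 ± 42.4, 45.6 ± 37.3, 32.8 ± 18 and 31.3 ± 32.2 CPM (n = 3). The ratios of pooled reads were 830 (149 to 32800) in F2, 957 (171 to 37800) in F3 and 358 (98.8 to 2970) in F4, and in F5, with 0 vehicle reads, at least 154-fold. Cyp1a2 was at least 19.3-fold higher in F1, 26.8-fold in F2, 20.7-fold in F3, 14.5-fold in F4 and 13.1-fold in F5. Without ICZ replicate 1, which held the most Cyp1a1 reads in F2 to F5, the Cyp1a1 ratios were 419 in F2, 494 in F3 and 274 in F4 and the F5 value at least 90-fold. Vehicle replicate 1 held the only vehicle read of Cyp1a1 in F2 and in F3, and without it the values there were at least 190-fold and 209-fold. Without vehicle replicate 2 the ratios were 534 and 613 and the F5 bound 98.1-fold, and without vehicle replicate 1 the F1 bound was 319-fold. For Cyp1a2 the F1 bound was 12.5-fold without vehicle replicate 1 and 9.84-fold without ICZ replicate 2. Without vehicle replicate 2 the Cyp1a2 bounds from F2 to F5 were 17.3, 13.3, 9.07 and 8.36-fold. A difference of the Cyp1a1 effect between fractions did not pass (edgeR, adjusted p = 0.957), nor did a slope along fraction number (-0.42 per fraction on the log2 scale, adjusted p = 0.975). With 0, 1, 1, 2 and 0 vehicle reads from F1 to F5, these tests cannot decide whether the effect differed.

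Over F2 to F5 added per mouse, 15497 genes were tested. Acta1, which encodes the alpha actin of skeletal muscle, went from 7.09 ± 0.14 to 39.6 ± 14.1 CPM with ICZ, a log2 fold change of 2.48 ± 0.24, and Mbl2, a mannose-binding lectin of innate immunity, from 5.33 ± 0.71 to 1.48 ± 0.55 CPM, -1.83 ± 0.27. All 29 proliferation genes had a positive fold change, with the S phase cyclin Ccna2 at 29.8 ± 3.49 and 42.8 ± 6.52 CPM. All 19 interferon response genes had a negative one, with the guanylate-binding protein Gbp7 at 22.6 ± 0.803 and 14.3 ± 0.623 CPM. The fold changes of all 17 intraepithelial T cell genes and all 7 MHC class II genes were negative too; Cd74, the invariant chain of MHC class II, stood at 155 ± 117 and 58.1 ± 5.85 CPM. The MHC class II median of -1.32 became -0.57 without vehicle replicate 1, and the T cell median of -0.60 became -0.38 without vehicle replicate 3. Within F5 the T cell median was positive, at 0.37, and it was 0.05 in F1. In edgeR without a block 0 genes passed, with a smallest adjusted p of 0.0535 and 886 genes at an unadjusted p under 0.05, where 775 are expected by chance. DESeq2 called 13, limma voom 5, edgeR with no filter on low counts 36 and edgeR with a crypt-villus score as a covariate 150. edgeR called 3 without vehicle replicate 1, 3 without ICZ replicate 1 and 1 without ICZ replicate 3.

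Same-numbered vehicle and ICZ mice deviated together in these sums, and their pairing was taken from the same counts. With the replicate number as a block edgeR called 231 genes, 116 higher and 115 lower with ICZ. Higher, in addition to Cyp1a1, were Acta1 (2.42 ± 0.20, adjusted p = 0.0116), the microvillar adhesion protein gene Tmigd1 (1.48 ± 0.20), the water channel gene Aqp8 (1.33 ± 0.17), Adgrd1 (0.93 ± 0.15), the lysoplasmalogenase gene Tmem86b (0.68 ± 0.07), the ribonucleotide reductase subunit Rrm2 (0.62 ± 0.09) and the dicarboxylate transporter Slc13a2 (0.60 ± 0.09). Lower were Mbl2 (-1.86 ± 0.21, adjusted p = 0.000319), Syne1 (-1.08 ± 0.22), Gimap6 (-0.97 ± 0.16), the ERK phosphatase gene Dusp5 (-0.85 ± 0.08), Laptm5 (-0.85 ± 0.15), the interferon-induced genes Ifit1bl1 (-0.84 ± 0.08) and Ifi44 (-0.82 ± 0.14), Rnd3 (-0.78 ± 0.08), Plk3 (-0.77 ± 0.17) and the T and NK cell surface receptor gene Cd160 (-0.73 ± 0.17). Under the block 10 of 29 proliferation genes rose, including Ccna2 (0.52 ± 0.07), 7 of 19 interferon genes fell, including Gbp7 (-0.66 ± 0.09), and 7 of 17 immediate early genes fell, including Hspa1a (53.2 ± 29.6 and 27.7 ± 17.5 CPM) and Jun (-0.56 ± 0.07). Villus tip genes fell in 4 of 16 cases, ER stress genes in 3 of 17, PPAR targets in 2 of 21 and T cell genes in 1 of 17, and 3 of 7 genes of the stroma list and 1 of 34 ribosomal protein genes rose. The genes named from the blocked fit were taken by the rule for named genes, applied after the values were seen.

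By camera 14 of 33 lists were called in the summed comparison, and none held with an estimated correlation. Higher were the AHR list, proliferation (median log2 fold change 0.31, adjusted p = 5.97e-14; adjusted p = 0.517 with an estimated correlation) and tuft cells (0.33, 11 of 11 positive; adjusted p = 0.443 with an estimated correlation). Enteroendocrine cells (0.22; adjusted p = 0.636 with an estimated correlation), stroma, endothelium and muscle (2.69 over 7 low genes; adjusted p = 0.458 with an estimated correlation) and ribosomal proteins (0.13; adjusted p = 0.95 with an estimated correlation) were also called higher. Lower were interferon response (-0.40), MHC class II (-1.32), intraepithelial T cells (-0.60), lower villus antimicrobial genes (-0.20) and PPAR targets (-0.10), with adjusted p = 0.443 with an estimated correlation for each of the 5. Immediate early and dissociation stress genes (-0.49), macrophages and dendritic cells (-0.71) and ER stress genes (-0.14) were called lower with adjusted p = 0.636 with an estimated correlation for each. Adjusted over the list alone, 3 T cell genes, 1 interferon gene and 0 proliferation, tuft, MHC class II and immediate early genes passed. Under the replicate block stem cell genes (0.14, adjusted p = 0.0135; adjusted p = 0.551 with an estimated correlation) and villus tip genes (-0.12, adjusted p = 0.00145; adjusted p = 0.516 with an estimated correlation) were called in addition. Without 1 of the mice 7 of the 14 calls were lost. Without ICZ replicate 1 these were enteroendocrine (camera adjusted p = 0.294), macrophage (0.11), immediate early (0.136), ER stress (0.447) and PPAR genes (0.101). Without vehicle replicate 3 they were enteroendocrine (0.174), macrophage (0.845) and ER stress genes (0.221). PPAR genes also lost the call without vehicle replicate 2 (0.0687). Antimicrobial genes lost it without ICZ replicate 3 (0.0593). Ribosomal protein genes lost it without vehicle replicate 1 (0.837), ICZ replicate 2 (0.175) or ICZ replicate 3 (0.467). The median of the stroma list became 0.69 without ICZ replicate 3. That of immediate early genes became -0.23 without vehicle replicate 3 and -0.26 without ICZ replicate 1, and that of enteroendocrine genes 0.11 and 0.04. That of macrophage genes became 0.21 without vehicle replicate 3, -1.16 without vehicle replicate 1 and -1.21 without ICZ replicate 3. That of ribosomal protein genes became 0.03 without vehicle replicate 1, 0.24 without ICZ replicate 1 and 0.02 without ICZ replicate 3. That of the AHR list became 0.00 without vehicle replicate 2 and 0.42 without vehicle replicate 3. That of interferon genes became -0.26 without vehicle replicate 1 and -0.61 without ICZ replicate 1.

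**Figure D3:**
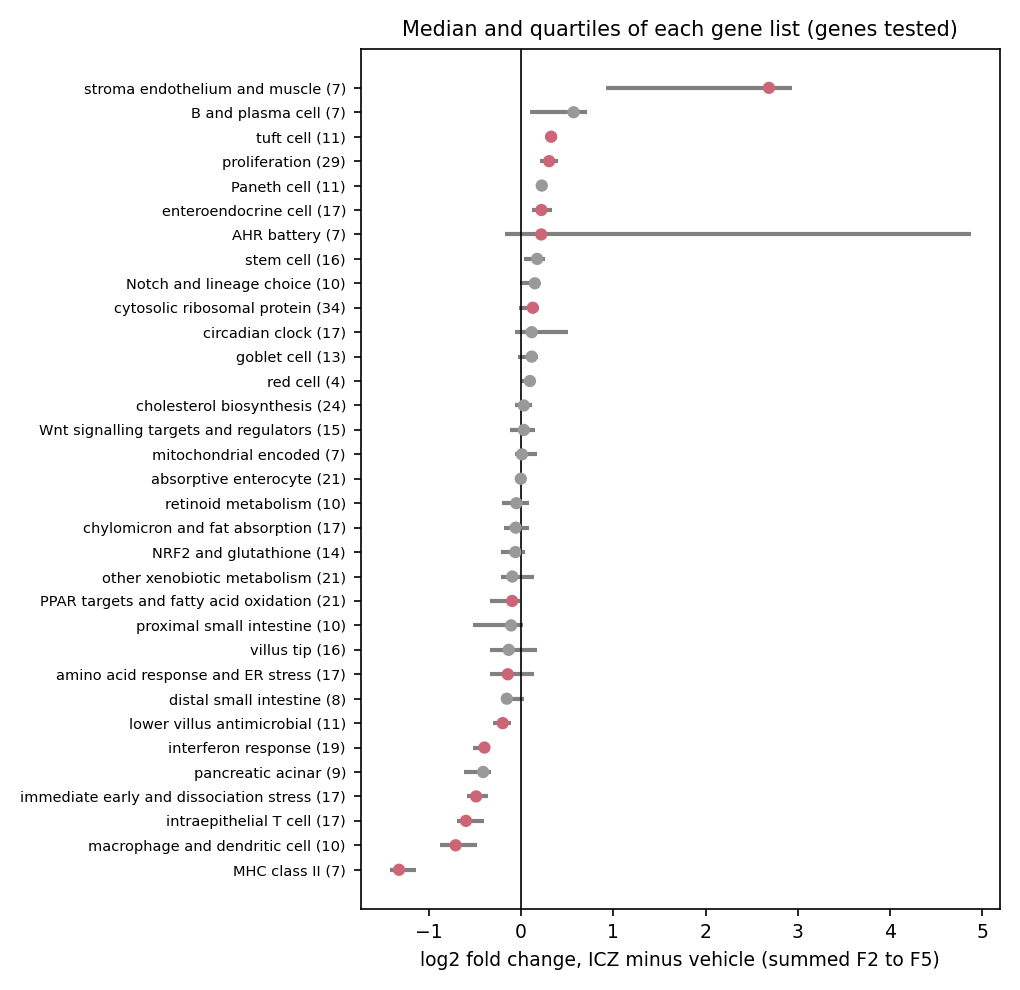
Median log2 fold change, ICZ minus vehicle, of each of the 33 gene lists in the summed comparison, with bars from the lower to the upper quartile of the list's genes and the number of tested genes in parentheses; coloured lists have a camera adjusted p under 0.05 with the preset correlation. The MHC class II list lies at -1.32 (-0.57 without vehicle replicate 1) and the proliferation list at 0.31, and none of the coloured lists holds with an estimated correlation.

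The other 19 lists were not called. Among markers of epithelial cell types the medians were 0.18 for stem cells, 0.23 for Paneth cells, 0.12 for goblet cells, -0.00 for absorptive enterocytes and -0.13 for the villus tip. Signalling and metabolic lists lay close to 0: Wnt 0.03, Notch 0.15, circadian clock 0.12, NRF2 -0.06, other xenobiotic metabolism -0.09, fat absorption -0.06, cholesterol synthesis 0.03 and retinoid metabolism -0.05. The proximal and distal intestine lists had medians of -0.11 and -0.15, mitochondrial transcripts 0.01, red cells 0.10, B and plasma cells 0.57 and pancreatic acinar genes -0.41. The mean lay on the other side of 0 from the median for villus tip (0.03) and retinoid genes (0.10), both with a camera direction of down, and for enterocyte genes (0.03), with a direction of up. For pancreatic acinar genes the mean was -0.43 while the camera direction was up.

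In F1, 4 genes rose with ICZ and 0 fell among 12335 tested. They were Cyp1a1 (edgeR, adjusted p = 0.00485), Bco1, which cleaves carotenoids to retinal, Tns4, an adhesion protein gene, and Tmem86b. Bco1 went from 40 ± 12.4 CPM (n = 3) to 204 ± 47.5 (n = 2), a log2 fold change of 2.37 ± 0.25 with an adjusted p of 0.0424. Tns4 went from 18.3 ± 3.61 to 45.6 ± 4.1 CPM (1.33 ± 0.18, adjusted p = 0.0141) and Tmem86b from 77 ± 9.67 to 172 ± 27.5 CPM (1.18 ± 0.14, adjusted p = 0.006). The difference was not confined to F1. Tmem86b values were higher with ICZ without overlap also in F2, F3 and F4, those of Tns4 in F2 and F3 and those of Bco1 in F3 and F5. In F3 Bco1 stood at 29.9, 6.47 and 9.62 CPM with vehicle and 50, 41.3 and 39 CPM with ICZ. None of these genes passed in F2 to F5. Bco1 (ENSMUSG00000031845.15) lies on chromosome 8 at 117095854 to 117133720, Tns4 (ENSMUSG00000017607.9) on chromosome 11 at 99065678 to 99089306 and Tmem86b (ENSMUSG00000045282.7) on chromosome 7 at 4628040 to 4631422. Without ICZ replicate 1 only Cyp1a1 of the 4 passed (Bco1 adjusted p = 0.17, Tns4 0.458, Tmem86b 0.25), and 1 gene was called in all; without vehicle replicate 1 the count was 22. DESeq2 called 18 genes in F1 and edgeR without the filter 57. Bco1 missed the threshold without vehicle replicate 2 (0.348), with other size factors (0.0531) and with a crypt-villus score as a covariate (0.0918), and Tns4 without vehicle replicate 2 (0.14), vehicle replicate 3 (0.0844) or ICZ replicate 2 (0.0673). In 1 fit over all 29 libraries Cyp1a1 (0.0606), Bco1 (1) and Tmem86b (1) missed it. The alternatives spanned 2.18e-159 to 0.0606 for Cyp1a1, 4.69e-50 to 1 for Bco1, 1.1e-08 to 0.458 for Tns4 and 6.89e-12 to 1 for Tmem86b.

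Lists of villus tip, enterocyte and enteroendocrine genes were called higher with ICZ in F1, and lists of Paneth, stem cell, Wnt and lower villus antimicrobial genes lower. Villus tip genes had a median log2 fold change of 0.33, with 13 of 16 positive (camera adjusted p = 7.38e-07; adjusted p = 0.227 with an estimated correlation). Enteroendocrine genes (0.27; adjusted p = 0.192 with an estimated correlation) and proximal intestine genes (0.17; adjusted p = 0.286 with an estimated correlation) were called higher as well. Fat absorption genes had a median of 0.21 (adjusted p = 0.524 with an estimated correlation) and enterocyte genes of 0.14 (adjusted p = 0.593 with an estimated correlation). Paneth (-0.58; adjusted p = 0.524 with an estimated correlation), stem cell (-0.33; adjusted p = 0.346 with an estimated correlation) and Wnt genes (-0.27; adjusted p = 0.267 with an estimated correlation) were called lower. So were MHC class II genes (-0.81; adjusted p = 0.593 with an estimated correlation) and antimicrobial genes (-0.22, 0 of 11 positive, camera adjusted p = 0.00651; adjusted p = 0.286 with an estimated correlation). Proliferation genes were called lower too, with a median of -0.22 and 5 of 29 positive (camera adjusted p = 0.0393; adjusted p = 0.8 with an estimated correlation). Ribosomal protein genes had a median of -0.17, 3 of 29 positive (camera adjusted p = 0.00188; adjusted p = 0.598 with an estimated correlation). Both lists were called higher in the summed counts and in F2, and this difference was not tested. Goblet, tuft, clock and other xenobiotic genes were called higher, with adjusted p = 0.593, adjusted p = 0.348, adjusted p = 0.593 and adjusted p = 0.598 with an estimated correlation, and each lost the call without ICZ replicate 2. In all, 17 lists were called and 0 with an estimated correlation, and 9 of the 17 lost the call without 1 of the mice. Enterocyte genes lost it without vehicle replicate 3 (median 0.09, adjusted p = 0.0692) or ICZ replicate 2 (0.01, adjusted p = 0.468). Proliferation genes lost it without vehicle replicate 1 (median 0.11, 0.123) or ICZ replicate 2 (-0.12, 0.468), and ribosomal proteins without vehicle replicate 1 (-0.02, 0.719) or ICZ replicate 2 (0.083). Paneth genes lost it without ICZ replicate 1 (median -0.35, 0.0746), and their median was -0.91 without ICZ replicate 2. The proliferation and ribosomal protein medians were -0.36 and -0.29 without vehicle replicate 2. The call was also lost by MHC class II genes without vehicle replicate 1 (median -0.18, 0.0787) or ICZ replicate 2 (0.083). The median of fat absorption genes was 0.11 without vehicle replicate 3, that of proximal genes 0.00, 0.39, 0.08 and 0.07 without vehicle replicate 1, vehicle replicate 3, ICZ replicate 1 and ICZ replicate 2, and that of antimicrobial genes -0.14 without ICZ replicate 1. The mean of enterocyte minus that of proliferation genes, a score of crypt-villus position, was 5.33 ± 0.54 with vehicle (n = 3) and 5.59 ± 0.23 with ICZ (n = 2) in F1, with an exact permutation p of 0.5.

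In F2, 2 genes fell with ICZ among 12115 tested and 0 rose. Ikzf2, which encodes the lymphocyte transcription factor Helios, went from 25.3 ± 6.13 to 6.43 ± 1.28 CPM (-2.04 ± 0.24, edgeR adjusted p = 0.0092) and Padi2, a protein arginine deiminase, from 8.47 ± 0.80 to 1.99 ± 0.45 CPM (-2.15 ± 0.31, adjusted p = 0.0497; n = 3 mice each). All 16 tested intraepithelial T cell genes had a negative fold change, with a median of -1.36; the T cell co-receptor gene Cd8a stood at 33.5 ± 15.5 and 12.9 ± 3.1 CPM and the chemokine Ccl5 at 234 ± 115 and 85.5 ± 31.8 CPM. Adjusted over the list alone 14 of the 16 passed, and 0 over all genes; under the replicate block 2 of the 16 fell over all genes. Proliferation genes were positive in 28 of 29 cases with a median of 0.52, and 22 passed adjusted over the list alone, 0 over all genes; under the block 7 of the 29 rose over all genes. The T cell list had a camera adjusted p of 1.7e-19 and the proliferation list of 4.23e-17, both with adjusted p = 0.519 with an estimated correlation. The crypt-villus score was 4.52 ± 0.23 with vehicle and 4 ± 0.72 with ICZ in F2, with an exact permutation p of 0.3 (n = 3 mice each). Within same-numbered pairs it was lower with ICZ in 3 of 3, with differences of -0.09, -0.42 and -1.07 and an exact sign permutation p of 0.25, two-sided, the smallest that 3 pairs allow. It differed by -0.15, -0.09 and -0.32 in F3, F4 and F5, with exact permutation p of 0.7, 1 and 0.8.

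Ikzf2 (ENSMUSG00000025997.13) lies on chromosome 1 at 69531214 to 69687245 and Padi2 (ENSMUSG00000028927.6) on chromosome 4 at 140906344 to 140952586. Both genes were also low in F3 without treatment. Vehicle F3 held 10.4, 7.35 and 9.78 CPM of Ikzf2, against 7.19, 7.14 and 4.96 CPM in ICZ F2. For Padi2 these values were 2.02, 2.92 and 2.72 CPM against 2.16, 2.33 and 1.47 CPM. Whether ICZ lowered the 2 genes or F2 held other cells with ICZ was not tested. Outside F2 the Ikzf2 values were lower with ICZ without overlap in F3 only, and the Padi2 values overlapped in every other fraction. In F5 Ikzf2 stood at 11.6, 11.4 and 6.48 CPM with vehicle and 42.4, 7.86 and 12 CPM with ICZ. Padi2 stood there at 6.8, 4.52 and 1.83 CPM against 8.27, 2.16 and 4.52 CPM (replicates 1 to 3 in order). Neither gene passed without vehicle replicate 2 (Ikzf2 adjusted p = 0.0745, Padi2 0.111), vehicle replicate 3 (0.071 and 0.228) or ICZ replicate 2 (0.068 and 0.199), and Padi2 also missed the threshold without ICZ replicate 3 (0.106). Neither passed in 1 fit over all 29 libraries (0.136 and 0.168), and the alternatives spanned 1.48e-15 to 0.136 for Ikzf2 and 2.5e-06 to 0.228 for Padi2. The F2 count was 267 without ICZ replicate 1, 13 without vehicle replicate 1, 20 with the crypt-villus score, 351 without the filter and 125 with DESeq2. Under the replicate block it was 221, 93 higher and 128 lower, and Cyp1a1, Cyp1a2 and Nqo1 rose in F2 with adjusted p = 1.4e-10, 0.00145 and 0.027. Acta1 also rose under the block, from 6.04 ± 3.99 to 62 ± 30.7 CPM (3.35 ± 0.17, adjusted p = 1.55e-09).

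Other lists called in F2 were Paneth cells (0.95; adjusted p = 0.519 with an estimated correlation), stem cells (0.45) and ribosomal proteins (0.30), the last 2 with adjusted p = 0.662 with an estimated correlation. Enteroendocrine genes were called higher (0.30; adjusted p = 0.351 with an estimated correlation), as was the AHR list (0.49; adjusted p = 0.294 with an estimated correlation). Interferon response genes (-0.49) and macrophage genes (-1.26) were called lower with adjusted p = 0.519 with an estimated correlation for both, and MHC class II genes (-1.14) with adjusted p = 0.662 with an estimated correlation. Under the block the goblet (0.14, adjusted p = 0.0454), B and plasma cell (-1.45, adjusted p = 1.3e-14) and immediate early lists (-0.15, adjusted p = 0.0476) were called in addition. With an estimated correlation these 3 had adjusted p = 0.547, 0.546 and 0.648 under the block. Without the block their medians were 0.13, -1.48 and -0.19, and these moved with single mice. Without vehicle replicate 3 the B and plasma cell median, over 4 genes, was 0.32 and the immediate early median 0.09, and without ICZ replicate 3 they were -3.15 and -0.49. The immediate early median was -0.43 without vehicle replicate 1, -0.32 without vehicle replicate 2, -0.11 without ICZ replicate 1 and -0.01 without ICZ replicate 2. The goblet median was 0.00 without vehicle replicate 1, 0.23 without vehicle replicate 3 and 0.05 without ICZ replicate 3. Genes called under the block over all genes were 2 of 11 Paneth, 1 of 15 stem cell, 1 of 12 goblet and 1 of 31 ribosomal protein genes, all higher. Lower were 3 of 4 B and plasma cell genes and 1 gene each of the interferon, macrophage and immediate early lists. Stem cell genes lost the call without ICZ replicate 3 (median 0.23, adjusted p = 0.121), as did ribosomal proteins (0.11, adjusted p = 0.162). MHC class II genes lost it without vehicle replicate 1 (-0.36, adjusted p = 0.0801) or ICZ replicate 3 (-0.84, adjusted p = 0.0882). Without ICZ replicate 3 the medians of the Paneth, interferon and AHR lists were 0.55, -0.31 and 0.20, and without vehicle replicate 3 that of macrophage genes was -0.65.

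In F3 Acta1 rose with ICZ, from 5.30 ± 2.16 to 38.8 ± 11.4 CPM (n = 3 mice each), a log2 fold change of 2.85 ± 0.30 with an edgeR adjusted p of 0.0257, and it was the only call among 12268 genes. The gene (ENSMUSG00000031972.5) lies on chromosome 8 at 123891769 to 123894751 on the minus strand. Acta1 means with ICZ were 123 ± 49.7 CPM in F1 (n = 2), 62 ± 30.7 in F2, 27.9 ± 9.66 in F4 and 26.6 ± 7.09 in F5, against vehicle means of 8.79 ± 5.46, 6.04 ± 3.99, 6.31 ± 2.91 and 9.78 ± 4.44. A slope of the Acta1 effect along fraction number, -0.58 ± 0.13 per fraction, did not pass (adjusted p = 0.238). The F3 call was lost without vehicle replicate 2 (0.212), vehicle replicate 3 (0.344) or ICZ replicate 2 (0.173) and in 1 fit over all 29 libraries (0.216), and the alternatives spanned 1.12e-42 to 0.344. In F3 498 genes were called without vehicle replicate 1 and 4 without ICZ replicate 1. The F3 count was 285 with the crypt-villus score, 221 without the filter and 12 with DESeq2, so the single call depends on these choices. The proliferation list was called higher in F3 (median 0.31) and interferon (-0.39), T cell (-0.56), MHC class II (-1.39) and antimicrobial genes (-0.20) lower, with clock genes (0.21) and the AHR list (0.42) higher. All 7 had adjusted p = 0.562 with an estimated correlation, and adjusted over the list alone 10 proliferation, 7 interferon and 4 T cell genes passed, against 0 over all genes. Without vehicle replicate 1 the MHC class II median was -0.50, without ICZ replicate 3 the proliferation median 0.20 and without vehicle replicate 3 the AHR median 0.81. Antimicrobial genes lost the call without vehicle replicate 1 (adjusted p = 0.0623) or ICZ replicate 3 (0.242), and clock genes without ICZ replicate 1 (0.0534) or ICZ replicate 2 (0.0564). The clock median was 0.37 without vehicle replicate 1 and the antimicrobial median -0.13 without vehicle replicate 2.

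**Figure D4:**
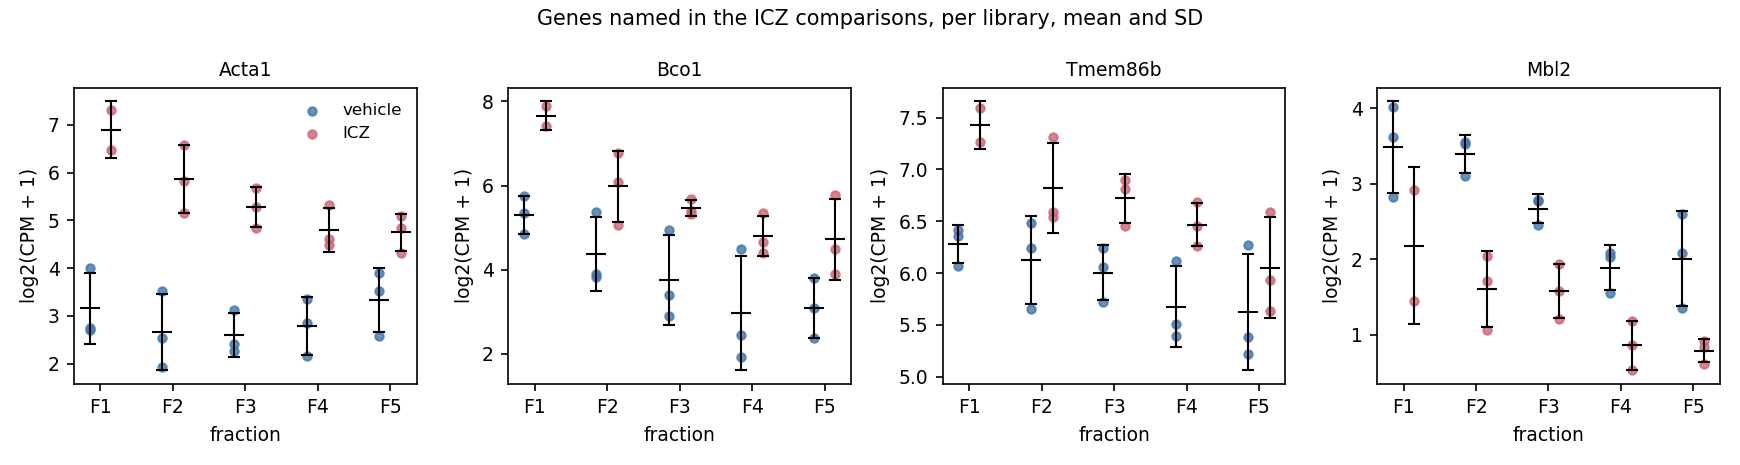
Log2(CPM + 1) of Acta1, Bco1, Tmem86b and Mbl2 in each library, by fraction and treatment; points are libraries, 1 per mouse and fraction, with horizontal lines at group means and error bars of 1 SD. Acta1 is 123 CPM on average with ICZ in F1 against 8.79 CPM with vehicle.

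In F4 and F5 no gene passed. The MHC class II list was called lower with ICZ in both, with medians of -1.29 in F4 (adjusted p = 0.534 with an estimated correlation) and -1.35 in F5 (adjusted p = 0.389 with an estimated correlation). These medians became -0.45 and -0.83 without vehicle replicate 1. The interferon list was called lower too, with medians of -0.29 (adjusted p = 0.671 with an estimated correlation) and -0.46 (adjusted p = 0.476 with an estimated correlation). Without vehicle replicate 2 the interferon medians were -0.47 in F4 and -0.17 in F5, and in F5 they were -0.72 without vehicle replicate 3 and -0.78 without ICZ replicate 1. In F4 the call was lost without vehicle replicate 1 (median 0.01, adjusted p = 0.839) and in F5 without ICZ replicate 2 (-0.13, adjusted p = 0.052). In F4 the AHR list was called higher (0.44, adjusted p = 5.88e-14; adjusted p = 0.054 with an estimated correlation), and antimicrobial (-0.28; adjusted p = 0.371 with an estimated correlation) and mitochondrial genes (-0.28; adjusted p = 0.639 with an estimated correlation) lower. In F5 tuft cell genes had a median of 1.00, all 9 positive (adjusted p = 0.44 with an estimated correlation), and immediate early genes of -0.71, all 17 negative (adjusted p = 0.456 with an estimated correlation), or -0.48 without ICZ replicate 1. Mitochondrial genes were called higher in F5 (0.56, 7 of 7 positive, camera adjusted p = 0.000367; adjusted p = 0.476 with an estimated correlation), at a mean log2 CPM of 13.56 ± 0.57 with vehicle and 14.05 ± 0.56 with ICZ (SD, n = 3 mice each). Without ICZ replicate 1, the F5 library with 54.3% of its reads in 10 genes, their median was 0.01 (adjusted p = 0.395). The call was also lost without vehicle replicate 3 (adjusted p = 0.0917), and the median was 0.91 without vehicle replicate 1. Intraepithelial T cell genes, lower in the summed counts, were called higher in F5 (0.37, 15 of 16 positive, camera adjusted p = 0.0172; adjusted p = 0.802 with an estimated correlation). Without ICZ replicate 1 they were called lower (-0.40, adjusted p = 0.00367), and without vehicle replicate 3 the call was lost (adjusted p = 0.439). Their F5 median was 0.61, 0.70 and 0.62 without vehicle replicate 1, ICZ replicate 2 and ICZ replicate 3. In F1 and F4 the T cell list was not called (0.05, adjusted p = 0.297, and -0.03, adjusted p = 0.959), and the difference between fractions was not tested. Proliferation genes were called higher in F4 (0.09; adjusted p = 0.955 with an estimated correlation) and F5 (0.25; adjusted p = 0.724 with an estimated correlation). Both calls were lost without vehicle replicate 1 (-0.05, adjusted p = 0.345, and 0.09, adjusted p = 0.169), and that in F5 also without ICZ replicate 2 (0.07, adjusted p = 0.666). The F4 median was 0.26, 0.15 and 0.14 without vehicle replicate 2, vehicle replicate 3 and ICZ replicate 1, and the F5 median 0.55 and 0.47 without vehicle replicate 3 and ICZ replicate 1. The list of stroma, endothelium and muscle was called higher in the ICZ F5 samples (median 3.51, 6 of 6 genes adjusted over the list alone, 0 over all genes; adjusted p = 0.389 with an estimated correlation). The F5 median of tuft cell genes was 0.44 without ICZ replicate 1 and that of the stroma list 1.49 without ICZ replicate 3, and the F4 call of mitochondrial genes was lost without vehicle replicate 1 (median -0.18, adjusted p = 0.165). In F1, F2 and F3 edgeR gave 542, 1455 and 1122 genes at an unadjusted p under 0.05, where 617, 606 and 613 are expected by chance. It called 0 of 12092 genes in F4, with 349 at an unadjusted p under 0.05 where 605 are expected. In F5 it called 0 of 12244, with 342 where 612 are expected. Counts in F4 and F5 thus lay below expectation. In F4 and F5 DESeq2 called 4 and 5, edgeR without the filter 26 and 37 and edgeR with the crypt-villus score 8 and 24. In F4 1 gene was called without vehicle replicate 1, ICZ replicate 1 or ICZ replicate 3, and in F5 1 without ICZ replicate 1. In all, 13 lists were called in F4 and 17 in F5, and 0 in either with an estimated correlation, and 10 and 12 of them were lost without 1 of the mice.

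Differences of the ICZ effect between the fractions were tested within mice. RP23-37C14.2 (ENSMUSG00000029882.5), a protein-coding gene on chromosome 6 at 41030268 to 41035509, was the 1 gene of 14067 whose ICZ effect differed between fractions (edgeR, adjusted p = 0.0359). It and the pancreatic carboxypeptidase gene Cpa1 (ENSMUSG00000054446.8, chromosome 6 at 30639218 to 30645363) had a slope along fraction number, of -4.70 (adjusted p = 0.00173) and -3.07 (adjusted p = 0.0117) per fraction on the log2 scale. Vehicle F5 replicate 3 held 332 CPM of RP23-37C14.2 and 133 CPM of Cpa1, the other 14 vehicle libraries 0 of both, and ICZ F5 replicate 3 held 238 and 85.9 CPM. The pancreatic acinar genes Prss2 and Cela3b stood at 252 and 164 CPM in that vehicle library and at 155 and 106 CPM in that ICZ library. The calls of RP23-37C14.2 and Cpa1 thus followed pancreatic transcripts in these libraries, and no ICZ effect on the epithelium can be read from them. The interaction count was 0 without vehicle replicate 3 or ICZ replicate 3, 4 without vehicle replicate 1 and 5 without ICZ replicate 1. The slope count was 0 without vehicle replicate 3, 17 without vehicle replicate 1, 6 without ICZ replicate 1, 11 without ICZ replicate 2 and 4 without ICZ replicate 3. Bco1 and Tmem86b, called in F1, had slopes of -0.05 (adjusted p = 0.994) and -0.10 (adjusted p = 0.889), so neither passed the slope test. A slope does not test an effect limited to 1 fraction. In the interaction test, which covers such an effect, only RP23-37C14.2 passed.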

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

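The results named here came from tests set before the data were examined, except the refit on F1 to F4 alone, which was chosen after the pancreatic transcripts in F5 had been seen. RP23-37C14.2 stood out because its ICZ effect differed between fractions (edgeR, adjusted p = 0.0359), with a slope of -4.70 per fraction on the log2 scale. The pancreatic carboxypeptidase gene Cpa1 stood out by its slope of -3.07 per fraction. Their levels were 332 and 133 CPM in vehicle F5 replicate 3, 238 and 85.9 CPM in ICZ F5 replicate 3, 11.5 and 4.5 CPM in ICZ F4 replicate 3 and 10.4 and 4 CPM in ICZ F5 replicate 1, and 0 in the other 14 vehicle libraries. The interaction count went to 0 without vehicle replicate 3 or without ICZ replicate 3, and the slope count to 0 without vehicle replicate 3. On F1 to F4 alone both counts were 0. The pancreatic acinar genes Prss2 and Cela3b were also high in the F5 libraries of vehicle and ICZ replicate 3. These calls thus followed pancreatic transcripts there, and no ICZ effect on the epithelium can be read from them.

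The 6 mice can be parted into 10 splits of 3 against 3, too few for a share under 0.05. For the interaction 4 of the 10 gave at least as many genes as the real split, which gave 1, and the highest other gave 78. For the slope 4 of 10 gave as many as the real 2, and the highest other gave 1316. Both high counts came from the split that put vehicle replicate 1 with ICZ replicates 1 and 3. They were several times the real count, and their cause was not tested. Since the replicate numbers were taken to pair the mice, the real split was also set against the 3 others that part every pair. These differ from it by exchanging the treatments within a single pair, and they gave at most 2 genes for the interaction and 3 for the slope.

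The sample whose label names no treatment or fraction stood out because it held Cyp1a1, at 16.8 CPM (126 reads), while the highest vehicle library held 0.18 CPM, both without TMM scaling. It also held 12 reads of Cyp1a2, or 1.6 CPM. The means over the 29 assigned libraries were 20.7 CPM and 1.35 CPM. Across 13093 genes, which are not independent replicates, its log2 CPM correlated at 0.995 with the mean of the 29 libraries and at 0.962 to 0.984 with single libraries. Of its reads 40.8% were assigned to genes and 31.9% were unaligned.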

How the results depend on the processing

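Alternatives limited to F2 to F4 or F1 to F4, the F4 against F1 contrast the list tests within a fraction and the pooled Cyp1a1 and Cyp1a2 folds with a mouse left out, and the F5 split with a library left out were chosen after the data had been seen; the others were planned. Counts of genes are given in the order summed, F1, F2, F3, F4, F5, where the main counts were 0, 4, 2, 1, 0 and 0. Without a filter on low counts they were 36, 57, 351, 221, 26 and 37, of which 0, 1, 11, 8, 9 and 12 were genes that the filter leaves out. DESeq2 called 13, 18, 125, 12, 4 and 5. With the replicate number as a block the counts were 231, 45, 221, 23, 5 and 8; F1 (with Acta1), F3, F4 and F5 do not meet the criterion for pairing, and there the block is a hint only. Of the summed and F2 calls that the block changed, those of the genes named and of the lists called there are given with the results. With the crypt-villus score as a covariate the counts were 150 summed, 5 in F1, 20 in F2, 285 in F3, 8 in F4 and 24 in F5. limma voom called 5 in the summed comparison, and 1 fit over 29 libraries called 2 in F1 and 0 in F3. Leaving out each mouse in turn gave 0 to 3 summed, 1 to 22 in F1, 0 to 267 in F2, 0 to 498 in F3, 0 to 1 in F4 and 0 to 1 in F5. For the interaction (1 gene) the count was 0 without the mouse block (no replicate block), 331 without the filter, 4 with DESeq2, 4 on F2 to F5, 0 on F1 to F4 and 0 to 5 with each mouse left out; for the slope (2 genes) it was 0, 81, 4, 18, 0 and 0 to 17 in that order. F5 against F1 gave 886 to 4215 genes when 1 mouse was left out and between 2841 and 4339 under its other alternatives, against 3703, with 2841 without the block. The higher share of calls was 52.9% with TMM and 50.5% with RLE. RLE size factors, F2 to F4 added, all fractions added and thinned libraries left the summed count at 0, and RLE gave 3, 2 and 1 in F1, F2 and F3. Called gene lists went from 14 summed, 17 in F1, 10 in F2, 7 in F3, 13 in F4 and 17 in F5 to 0 in each with an estimated correlation; fry gave 0, 0, 1, 0, 1 and 0. In F5 against F1 they went from 19 to 1 with an estimated correlation and to 23 with fry. Summed list calls lay between 14 and 20 with a mouse left out. Arnt, at -0.06 summed, turned to 0.054 with the score, 0.088 without vehicle replicate 1 and 0.006 without ICZ replicate 3, and lay between -0.182 and 0.088 with a mouse left out. Of the values of named genes under the alternatives 354 kept direction and side of the threshold, 40 newly passed it, 37 fell short of it and 3 turned sign. Except where stated the cause was not tested. No library fell under the limit set for shallow libraries, so the alternative without shallow libraries was not run. Depth limits genes such as Ahrr, Cyp1b1 and Aldh3a1, with at most 47 reads per group in the summed counts.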

Other observations

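Chosen after results had been seen were the count of genes moving one way in every fraction from F2 to F5, the tests of time in the buffer and of T cell number, the levels of Acta2 and Actg2, the fold changes of actin genes by fraction, the tests limited to F1 to F3, F1 to F4 or F5, the F5 split with a library left out, and the setting of each score fit against the fit without the score on the same mice; the other tests of the 3 patterns were written before their values were seen.

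Of 11525 genes tested in each of F2 to F5, 11 had an unadjusted p under 0.05 and a common direction in all 4 fractions, and each kept its sign in F1. Higher with ICZ were Cyp1a1, Acta1, the adhesion protein gene Tmigd1 (summed log2 fold change 1.42), the adhesion receptor Adgrd1 (0.93), the laminin subunit Lamb3 (0.81) and the epoxygenase Cyp2j6 (0.49, from 109 ± 13.1 to 153 ± 8.39 CPM; SD, n = 3 mice each). Lower were Mbl2, the sodium-proton exchanger Slc9a3 (-0.58, from 64.6 ± 13.3 to 43.2 ± 6.57 CPM), RP23-441L19.1 (-0.56), the ubiquitin ligase Dtx3l (-0.49) and the ER chaperone Hspa5 (-0.41, from 1320 ± 226 to 988 ± 47.5 CPM). Under the replicate block the summed adjusted p was 0.00136 for Cyp2j6 and 0.0288 for Hspa5; all 11 were chosen on the same counts, so these values add no support. Fractions of a mouse are not independent, so this count has no p of its own. Among the 10 splits of the mice 4 gave at least 11 such genes. The highest other gave 47, with vehicle replicates 1 and 2 and ICZ replicate 1 on a side, and its cause was not tested. The 3 others that part every same-numbered pair gave at most 1.

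Acta1 was higher with ICZ in all fractions, by 2.48 ± 0.24 in the summed counts. Crypt-villus position is argued against as its cause, since with the position score as a covariate the fold change was 2.58 ± 0.20. Muscle in the ICZ samples was tested with 10 skeletal and 7 smooth muscle genes, 5 of which also stand in the stroma list; apart from the widely expressed Aldoa, the highest means over ICZ libraries were 4.18 CPM for Mylpf, which stood at 4.29 CPM with vehicle, and 1.14 CPM for Acta2. The median of a list reached 10.2% of Acta1 in ICZ F5 replicate 3, just over the bound of 10%, so over all ICZ libraries muscle cannot be told apart from a response to ICZ; F1 to F4 reached at most 1.44%, which argues against muscle there, while in F5 it stays open because of the smooth muscle genes of that 1 library, with the other 2 at 1.61% and 2% and the skeletal muscle median at 0 in all 3. Reads shared with other actin genes were undecided over all fractions. Actb and Actg1 had a summed log2 fold change of at most 1.34 (2 SE) against at least 2.01 for Acta1. In F1 to F3 Acta2 and Actg2, too low for the fit, together reached at most 0.962% of Acta1. Actg1, the higher of the other 2, had upper bounds there of 1.07, 1.97 and 1.48 against lower bounds of 2.74, 2.13 and 2.26 for Acta1. These values argue against reads shared with these actin genes in F1 to F3, and further actin genes were not tested. Actg1 itself stood at only 2.06 CPM with vehicle and 2.99 with ICZ in the summed counts. Since reads of low mapping quality were left out, shared reads as such are not excluded. In F4 they stay open, with 1.57 against 1.46 and up to 9.62%. In F5 they also stay open, at 50.3% in ICZ replicate 3 and 2.42% and 4.67% in the others. A response of Acta1 to ICZ in F1 to F3 may remain as a hypothesis.

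Immediate early and dissociation stress genes were higher in F5 than in F1 of vehicle mice, with a median log2 fold change of 1.86. With the crypt-villus score as a covariate the median was 1.64. With a mouse left out it was 1.51 to 2.06, against 1.85 to 2.01 without the score. That fit also held mouse and fraction terms, so the score acted only through differences between libraries of a fraction. It therefore cannot decide whether crypt-villus position alone set the pattern. Longer time in the dissociation buffer cannot be told apart from other differences between early and late fractions: the list level was higher in F5 than in F2 in 6 of 6 mice, but lower in F2 than in F1 in 5 of 5. No biological explanation was tested.

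Intraepithelial T cell genes were lower with ICZ in F2, with a median of -1.36. A single mouse as the cause is argued against, since the median closest to 0 with a mouse left out was -0.98, without vehicle replicate 3. With the crypt-villus score as a covariate the median was -1.24, and with vehicle replicate 3 left out, where the score moved it furthest, -0.61 against -0.98. This fit rests on 1 score and few libraries, so it cannot decide whether F2 held other cells with ICZ. The mean log2 CPM of the list was 3.22 ± 0.53 in ICZ F2, 4.44 ± 0.56 in vehicle F2 and 3.45 ± 0.25 in vehicle F3 (SD). Paneth genes in ICZ F2 also lay nearer vehicle F3 (7.53 against 7.78, and 6.71 in vehicle F2). Enterocyte genes did not (9.11 against 8.80, and 9.09 in vehicle F2). Position thus stays open. Fewer T cells in the ICZ F2 samples cannot be told apart from lower expression: 100% of the listed genes with at least 5 CPM in vehicle F2, 15 of 15, had negative fold changes, the most abundant being Gzma (315 ± 139 and 126 ± 43.5 CPM) and Ccl5 (234 ± 115 and 85.5 ± 31.8 CPM), but this direction was known when the test was chosen. Whether ICZ or the release of cells set it was not tested.

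The splits of the mice were also run for the other comparisons, where 10 splits of 3 against 3 are too few for a share under 0.05. In the summed comparison, with 0 genes in the real split, all 10 gave as many and the highest other gave 0. In F2 the real split gave 2 genes, 1 of the 10 splits, the real one, gave as many, and the highest other gave 1. In F3 the real split gave 1, 2 of 10 splits gave as many, and the highest other gave 8. In F4 and F5, with 0 genes, all 10 gave as many, and the highest others gave 2 and 1003. The split with 1003 genes in F5 put vehicle replicates 1 and 2 with ICZ replicate 1, and that with 8 in F3 put vehicle replicate 1 with ICZ replicates 1 and 2. The 1003 in F5 came from a split other than treatment, and they rest on vehicle replicate 3, without which the count was 0. It was 34, 232 and 1030 without ICZ replicate 2, 3 and 1, and 297 and 1488 without vehicle replicate 1 and 2. What set these counts was not tested. The 3 other splits that part every same-numbered pair, each of which exchanges the treatments within a pair, gave 0 genes in each of these comparisons. With the replicate number as a block in the summed comparison the real split gave 231 genes, and of the 4 splits that part every pair 1, the real one, gave as many; the highest other gave 3. F5 against F1 gave 3703 genes, reached in 1 of 10 splits, the real one, and the highest other gave 0, also among those that part F5 from F1 in every mouse.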
